A study of Homo sapiens with 4 samples.

How the data were processed

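Single-cell RNA libraries of the human breast cancer line MDA-MB-231 were made with 10x Chromium 3' chemistry, which tags each captured transcript near its polyadenylated end with a cell barcode and a unique molecular identifier (UMI). There were 4 libraries, of which 2 carried the label WT and 2 the label KO, for knockout of mdig (also MINA53, gene symbol RIOX2). The deposited matrices hold UMI counts per gene and barcode, whole numbers without normalization, and the deposited lists of barcodes and genes hold other content than measurements, namely names in the order of the matrix. The matrices were unfiltered, with 2846904 to 3160478 barcodes listed per library. The submitters' notes name Cell Ranger 6.1.1 and the build hg38, whereas the matrix headers name Cell Ranger 4, and the release of the gene annotation was not stated. The reference held 36601 genes, 10 of whose symbols were shared by more than 1 Ensembl identifier. Coordinates are those of GENCODE release 29 on GRCh38, matched by Ensembl identifier, which placed 19570 of the 20089 genes tested. The labels do not say that the replicates came from separate cultures or separate knockout clones, so p-values measure only the spread between these 4 libraries.

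Barcodes were called as cells when their UMI total reached at least 1 part in 10 of the 99th percentile among the 3000 largest barcodes of the library. This gave thresholds of 17325 UMIs in WT replicate 1, 16210 in WT replicate 2, 18880 in KO replicate 1 and 16421 in KO replicate 2. Cells with fewer than 500 genes or more than 20% mitochondrially encoded UMIs were left out, and the second limit removed 4.35%, 4.63%, 4.37% and 7.29% of called cells in the same order. Scrublet (in scanpy 1.11.5, expected rate 0.06) marked 0, 1, 4 and 0 cells as doublets. These shares lay under the 0.5% fixed as the least for a working call, so no doublets were removed and doublets remain among the cells. Shares of cells are given with exact Clopper-Pearson 95% intervals, which cover counting error only, and beside a count of 0 stands the share that 3 cells would make. RNA outside cells was read from barcodes with 100 to 400 UMIs.

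Counts were summed over the cells of each library, and the library was the unit of replication. Genes were tested with the edgeR 4.0.16 quasi-likelihood method (R 4.3.3), with TMM normalization, the default low-count filter and genotype as the only term. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Fold changes are log2, KO-labelled over WT. Their standard errors (SE) were derived from the size of the change and its F statistic. Levels are CPM, the UMIs of a gene scaled to the UMI total of its library, as mean ± SD over 2 libraries. In counts simulated with the fitted dispersion, edgeR recovered 26% of genes changed by 1.25-fold, 68.1% at 1.5-fold, 81.2% at 2-fold and 94% at 4-fold. It called 5 of 19547 unchanged genes, and camera found the shifted list of 40 genes and 0 of 20 unshifted lists. Genes were simulated independently of each other, so this does not show how often camera falsely calls lists of correlated genes.

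The 24 gene lists covered mesenchymal and EMT genes, extracellular matrix and collagens, epithelial genes, MDA-MB-231 metastasis genes, TGF-beta and YAP targets, neuropilins and glycan metabolism, NF-kB and inflammatory cytokines, interferon response, antigen presentation, ribosome biogenesis and nucleolus, MYC targets, histone methylation enzymes, cancer-testis antigens, G1/S and S phase, G2/M, glycolysis and hypoxia, NRF2 with glutathione and the pentose phosphate pathway, unfolded protein and amino acid stress, cholesterol and fatty acid synthesis, immediate early and heat shock genes, mitochondrially encoded genes, nuclear oxidative phosphorylation, cytosolic ribosomal proteins and ZNF zinc fingers. Lists were compared with the other genes by camera (limma 3.58.1, preset correlation 0.01), and again with the correlation estimated for each list. The estimated form also takes its degrees of freedom from the 4 libraries, which leaves few. Fry tests whether the genes of a list move, on balance, one way, and its mixed form whether they change in either direction. Neither form of fry compares a list with other genes or lists. A set of 9 marker lists looked for cells of another type.

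The genes named were RIOX2, the 8 largest rises and the 8 largest falls among called genes, and 2 members of each list with the largest changes. They had to reach a mean of 10 CPM in the higher group, show no overlap between the libraries of the 2 groups and carry a symbol that is neither a clone identifier nor sex-specific. A list without such a member would have been represented by its most abundant gene. A gene named under 2 parts of the rule counts under both, and 3 genes that the rule named are not reported here, which left 54 genes beside RIOX2. The samples, lists, tests, naming rule and the first group of other settings below were fixed before the data were examined.

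Cell cycle scores (scanpy) used the lists for S phase and G2/M, with each cell thinned to 10000 UMIs so that depth was equal, and the shares of the 4 libraries were compared by a two-sided exact permutation test. A score for the other genotype used genes that differed between 1 WT and 1 KO-labelled library and was applied to the remaining pair, with the midpoint between the library medians as the limit. A single pair of libraries allows no test, so these genes were taken as those with at least a 2-fold difference and 10 CPM, with a pseudocount of 0.1 CPM, in place of called genes.

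After the data had been seen, the cells of each genotype were split along the first principal component of the 2000 most variable genes. RIOX2, cell cycle genes, mitochondrially encoded genes, ribosomal protein genes and genes with a correlation above 0.2 with the cycle scores were left out of this split. The smaller side was named subpopulation 2, and cells in the middle 1 of 3 equal parts of the distance between the 2 centres were left unassigned. The numbers 1 and 2 do not pair the subpopulations of WT with those of KO. The split was made on expression, so most genes differ between its sides by construction, and values within subpopulations describe the split.

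The first group of other settings held DESeq2 1.42.0, total library size without TMM, no low-count filter, cell calling at 2000 or 5000 UMIs, no mitochondrial maximum or one of 10%, no doublet removal, thinning to the smallest library, G1-like cells only, the replicate number as a block, and leaving out each library in turn. Comparisons with single subpopulations, a crossed pairing of replicates and removal of the 5% of cells with most UMIs were added after the data had been seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the remaining steps.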

Results

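Gene expression was measured cell by cell in MDA-MB-231, a triple-negative human breast cancer line of mesenchymal character, in 2 libraries labelled wild type (WT) and 2 labelled knockout (KO) for mdig. Mdig, encoded by RIOX2, is a ribosomal oxygenase of the nucleolus that has also been studied as a histone demethylase. WT replicates 1 and 2 gave 5148 and 4096 cells from totals of 328087616 and 248830039 UMIs. KO replicates 1 and 2 gave 4445 and 4758 cells from 307039104 and 296962373 UMIs. Median depth per cell was 48861, 46406, 54722 and 46444 UMIs in the same order, and the median share of mitochondrially encoded UMIs was 9.30%, 9.50%, 8.74% and 9.89%. Cells held 84.3 to 88.2% of all UMIs, and no gene took more than 1.94% of the UMIs of a library.

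The first comparison asked whether the transcript of the targeted gene differed between the genotypes. RIOX2 was higher, not lower, in the libraries labelled KO, at 35.8 ± 1.51 CPM against 25.8 ± 1.85 CPM in WT (SD, n = 2 libraries each). The change was 0.42 on the log2 scale (SE 0.07), or 1.34-fold, with an adjusted p of 0.00154 in edgeR, and both KO-labelled libraries lay above both WT libraries. The gene (ENSG00000170854) is protein coding and lies on the minus strand of chromosome 3, from 97941818 to 97972457 on GRCh38. The labels do not state which part of it was altered, and a 3' tag count does not test a frameshift knockout, in which the transcript can persist. The level of RIOX2 therefore neither bears out the KO label nor speaks against it, and the groups are called KO-labelled and WT. In the names of replicates and subpopulations KO stands for this label, and genotype means the labelled genotype.

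Counts of RIOX2 per cell reached further in the KO-labelled libraries. At full depth a RIOX2 UMI was found in 65.0% (63.7 to 66.3%) and 67.0% (65.6 to 68.5%) of WT cells and in 66.5% (65.0 to 67.8%) and 64.5% (63.1 to 65.9%) of KO-labelled cells. With every cell thinned to 10000 UMIs the shares were 22.05% and 23.6% in WT against 25.7% and 27.7% in KO-labelled libraries. The highest count in 1 cell was 15 UMIs in each WT library and 72 and 60 UMIs in the KO-labelled libraries. RNA outside cells carried RIOX2 at 27.5 and 28.5 CPM in WT and at 28.6 and 29.6 CPM in KO-labelled libraries. No cell type in these libraries is known to lack the gene, so the share that free RNA alone would give was not measured in cells. The change of RIOX2 was 0.81 on the log2 scale among G1-like cells. It was 0.87 for subpopulation 1 and -1.47 for subpopulation 2 of the KO-labelled cells, each against all WT cells, so its direction turned between these groups of cells, which were defined after the data had been seen.

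The cells of each genotype were split into a pair of subpopulations, and in the KO-labelled libraries these differed in RIOX2. Subpopulation 1, with 58.4% and 61.1% of the cells of KO replicates 1 and 2, had RIOX2 at 46.8 and 48.8 CPM. Subpopulation 2, with 30.3% and 27.3% of cells, had it at 9.08 and 10.6 CPM. The difference was -2.36 on the log2 scale (SE 0.04), a level 5.13-fold higher in subpopulation 1, with an edgeR adjusted p of 6.27e-31 with the library as a block and 3.3e-06 without it. RIOX2 itself took no part in defining the subpopulations. In thinned cells a RIOX2 UMI was seen in 33.3% and 35.9% of subpopulation 1 and in 6.46% and 6.93% of subpopulation 2. Subpopulation 2 held 0.605 and 0.62 RIOX2 UMIs per cell. At the median UMI total of the barcodes read for free RNA, such RNA would give 0.00678 and 0.00864 RIOX2 UMIs per cell. This estimate takes a droplet with a cell to hold as much free RNA as those barcodes, which was not measured.

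In the WT libraries the corresponding split moved RIOX2 little. WT subpopulation 1, with 44.0% and 43.0% of cells, had 26.1 and 28.6 CPM, and WT subpopulation 2, with 39.6% and 40.5%, had 22.1 and 24.2 CPM. This difference was -0.14 on the log2 scale with an adjusted p of 0.00202 in edgeR. The first principal component took 4.23% of the variance of the genes used in WT and 5.47% in KO-labelled cells. A split made from 1 library alone put 100% of the cells assigned by both on the same side. This covered 4209 of 5148 and 3342 of 4096 WT cells, and 3901 of 4445 and 4134 of 4758 KO-labelled cells. Both splits used the same cells, and cells in the middle of either were left out, so high agreement was favoured by construction. The median mitochondrial share was 11.2% and 13.0% in KO subpopulation 2 and 7.96% and 9.12% in KO subpopulation 1. The 3' end of RIOX2 overlaps CRYBG3, a gene on the opposite strand, by 3146 bases, and CRYBG3 changed by 0.13 between genotypes (adjusted p of 0.258 in edgeR) and by -0.61 between KO subpopulations 2 and 1.

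**Figure D1:**
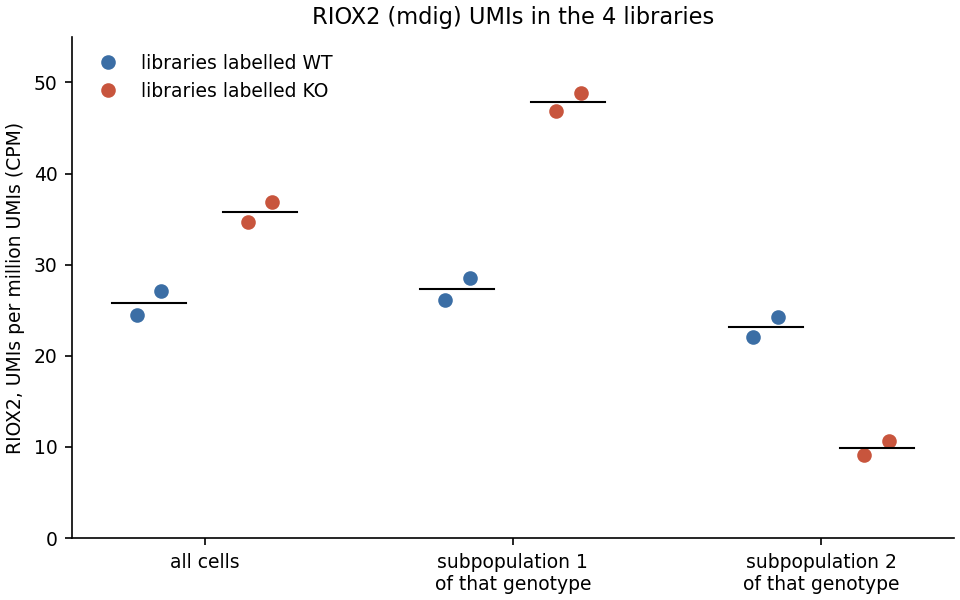
RIOX2 level in CPM for each library (points, with the mean of 2 libraries as a line), over all cells and within the subpopulations of each genotype. KO-labelled libraries reach 46.8 and 48.8 CPM in subpopulation 1 and 9.08 and 10.6 CPM in subpopulation 2, whereas all WT values lie between 22.1 and 28.6 CPM.

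**Figure D2:**
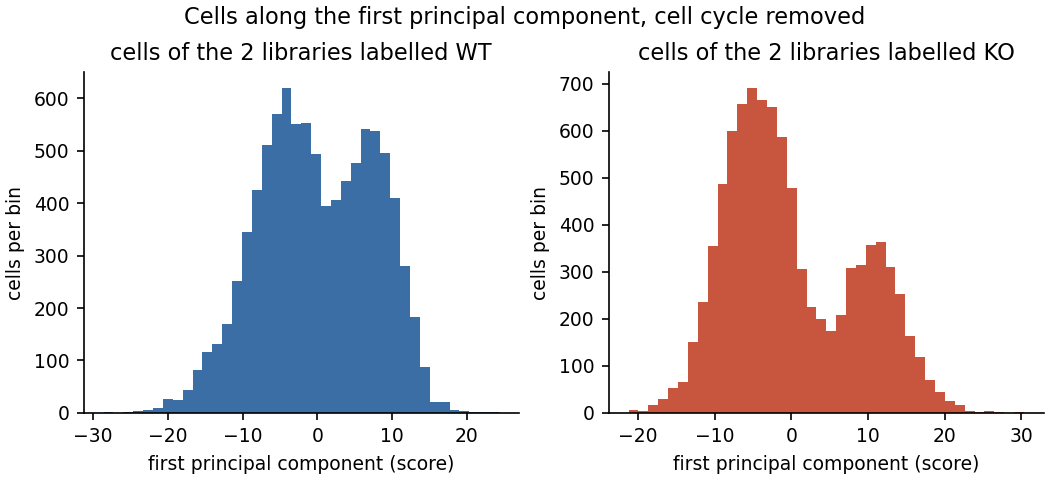
Number of cells along the first principal component (score, cell cycle removed) in the 2 WT libraries and in the 2 KO-labelled libraries. The component takes 4.23% of the variance in WT and 5.47% in KO-labelled cells, and the smaller group, on the right, is subpopulation 2.

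The second comparison asked which genes differed between KO-labelled and WT cells. Among genes that reached 10 CPM in the higher group, the 2 largest rises were in genes of antigen presentation to T cells by MHC class II. HLA-DRA, the alpha chain of HLA-DR, rose from 1.40 ± 0.00765 to 28.0 ± 0.255 CPM, a log2 change of 4.27 (SE 0.08), and its partner HLA-DRB1 rose by 3.89. CD74, the invariant chain that chaperones class II molecules, rose by 2.22. Under the same limit the 2 largest falls were in THY1, a surface glycoprotein used as a stromal and stem cell marker, and PLCB4, a phospholipase C of G protein signalling. THY1 went from 12.7 ± 1.44 to 0.0292 ± 0.0152 CPM (log2 change of -8.81, SE 0.18) and PLCB4 from 26.4 ± 1.39 to 0.170 ± 0.0149 CPM (-7.32, SE 0.10). HLA-DRA (ENSG00000204287) lies on chromosome 6 from 32439842 to 32445046, THY1 (ENSG00000154096) on chromosome 11 from 119417378 to 119424985, and PLCB4 (ENSG00000101333) on chromosome 20 from 9068763 to 9481242, all protein coding.

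Among the other large rises, MAGEB2, a cancer-testis antigen of the X chromosome, rose by 3.14 and TNC, the matrix glycoprotein tenascin C, by 2.19. CARD16, an inhibitor of caspase-1, rose by 2.21, ADIRF, a regulator of fat cell differentiation, by 2.12 and the long noncoding RNA APCDD1L-DT by 2.30. Among the other falls, IL24, a cytokine, fell by 3.12 on the log2 scale. GAL, the neuropeptide galanin, fell by 2.76, the sperm-associated antigen SPANXC fell by 2.34, its relative SPANXB1 fell by 2.25, and NRIP1, a corepressor of nuclear receptors, fell by 1.97. Adjusted p-values of these 15 genes in edgeR ran from 5.58e-10 to 2.78e-05. The naming rule admitted only called genes without overlap between the libraries of the genotypes. HLA, MAGE, SPANX and SSX genes have close paralogs that share sequence, so a count can hold UMIs of a relative.

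In all, 6971 of 20089 tested genes (34.7%) were called, 3554 higher and 3417 lower in the KO-labelled libraries. A change of at least 2-fold was seen in 1359 of them, 680 higher and 679 lower. The libraries of the genotypes did not overlap for 66.7% of tested genes, where chance gives 33.3%. With total library size in place of TMM the higher genes made up 61.3% of calls against 51.0%, and the median change over all genes moved from -0.01 to 0.04. Chromosomes differed in their typical change, with medians of 0.36 on chromosome 4, 0.35 on chromosome 15, 0.16 on chromosome 6, which carries the HLA genes, and -0.16 on chromosome 12. Without KO replicate 2 the number of calls was 4629, with 2206 lower, and without KO replicate 1 the number lower was 2243.

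**Figure D3:**
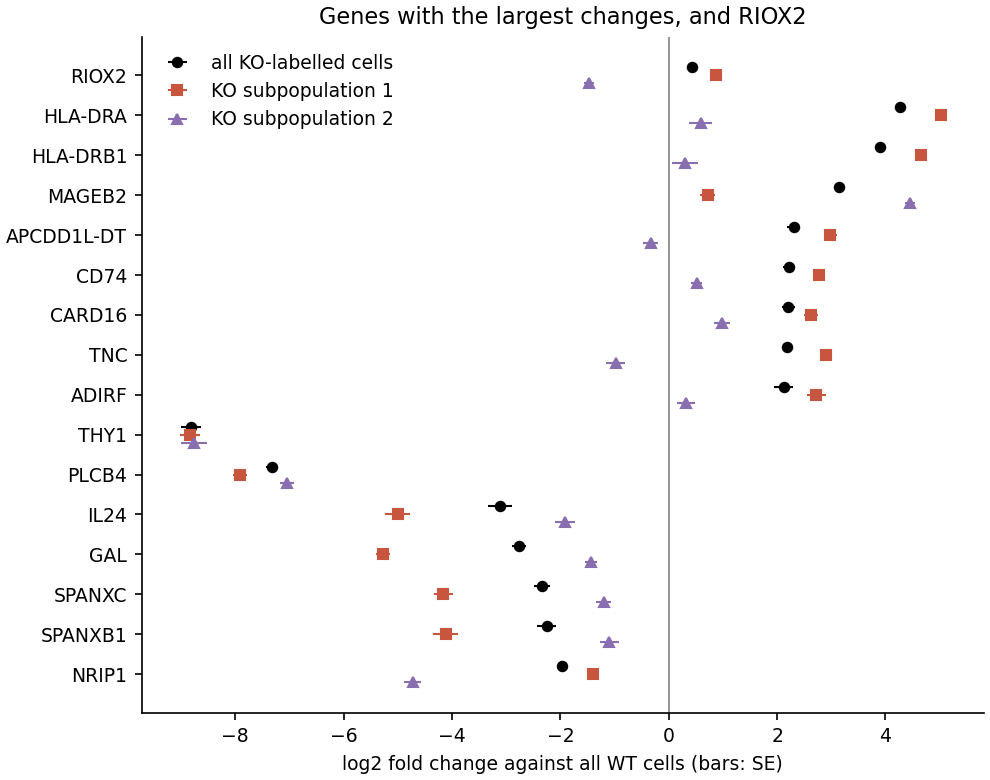
Log2 fold change (bars, SE) of the 8 largest rises, 7 of the 8 largest falls (among genes that reached 10 CPM) and RIOX2 against all WT cells, for all KO-labelled cells and for each KO subpopulation. HLA-DRA stands at 4.27 over all cells, 5.02 in subpopulation 1 and 0.59 in subpopulation 2, and THY1 stands at -8.81 over all cells and at -8.83 and -8.76 in the subpopulations.

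The subpopulations of the KO-labelled cells carried these changes unequally. Against all WT cells, HLA-DRA was at 5.02 in KO subpopulation 1 (adjusted p of 6.62e-10 in edgeR) and at 0.59 in subpopulation 2 (adjusted p of 0.0569). The subpopulations differed by -4.46 with an adjusted p of 1.21e-30 in edgeR. HLA-DRA and the other genes named in this paragraph could take part in defining the split, so such values describe it and are no independent evidence. TNC was at 2.91 in subpopulation 1 and at -0.98 in subpopulation 2. MAGEB2 was at 0.72 and 4.46, and SSX1, another cancer-testis antigen, at -1.96 and 2.64. These genes also differed between the WT subpopulations, by -2.54 for HLA-DRA, -1.94 for TNC, -2.49 for MAGEB2 and -4.23 for SSX1 (log2, subpopulation 2 minus 1). All of them went the same way in WT. Between the KO subpopulations HLA-DRA (-4.46) and TNC (-3.91) went the other way from MAGEB2 (3.72) and SSX1 (4.59). THY1 and PLCB4 were lower in both KO subpopulations, with PLCB4 at -7.91 and -7.04. KISS1, a metastasis suppressor, was at -3.24 in subpopulation 1 and at 0.40 in subpopulation 2. Of 18570 genes tested in both, 1327 were called higher and 1306 lower in both subpopulations, and 1071 were called in opposite directions. Independent calls would give 668, 719 and 1387, and both comparisons shared the WT libraries. In counts simulated without change the shared WT libraries alone gave a correlation of the log2 changes of 0.389 and the same sign in 64.8% of genes, against 0.395 and 60.9% observed, and a covariance of 0.0181 against 0.226 observed. The highest number of shared calls in 20 such simulations was 0. Counts simulated without change hold almost nothing to call, so this 0 was set in advance. It does not show whether the shared calls observed exceed what shared WT libraries give among changed genes. The simulated correlation and share of the same sign are those of noise alone, so they set no baseline for the observed ones.

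The gene lists grouped the changes by function, and antigen presentation stood out. In this list 19 of 20 members rose, and as many adjusted over the list alone, with a median log2 change of 0.83 and a camera adjusted p of 4.5e-11, which became 0.834 (unadjusted 0.0899) with an estimated correlation of 0.27. Extracellular matrix genes followed, with 19 of 29 higher and 3 lower (20 and 4 adjusted over the list alone), a median of 0.61 and an adjusted p of 6.06e-06, which became 0.834 with an estimated correlation of 0.446. Its largest changes among members that reached 10 CPM were in TNC and in COL18A1, a basement membrane collagen that rose by 1.34. Glycolysis and hypoxia genes had 21 of 33 members higher and 3 lower (22 and 3 adjusted over the list alone), a median of 0.33 and an adjusted p of 8.99e-06, which likewise became 0.834. CA12, a carbonic anhydrase, rose by 1.47, and P4HA1, a subunit of collagen prolyl hydroxylase that is induced by hypoxia, by 0.88.

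A pair of further lists was higher with smaller medians under the preset correlation of camera, and both calls were lost with an estimated one (adjusted p of 0.834 each). Mesenchymal and EMT genes had 10 of 23 members higher and 2 lower (11 and 2 adjusted over the list alone), with a median of 0.23 (0.385 without KO replicate 1 and 0.156 without KO replicate 2) and an adjusted p of 0.0266. S100A4, a calcium-binding protein of motile cells, rose by 1.31, and MMP14, a membrane-bound matrix metalloproteinase, by 1.13. Neuropilins and glycan metabolism had 18 of 40 higher and 3 lower (18 and 4 adjusted over the list alone), with a median of 0.19 and an adjusted p of 0.0203. HAS2, a hyaluronan synthase, rose by 1.18 and HS3ST1, a heparan sulfate sulfotransferase, by 0.74.

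A set of 4 lists for protein synthesis and respiration was lower under the preset correlation of camera, and each call was lost with an estimated one (adjusted p of 0.834 to 0.896). Ribosome biogenesis and nucleolus, where mdig itself resides, had 19 of 35 members lower and 1 higher (20 and 1 adjusted over the list alone), a median of -0.26 and an adjusted p of 0.00134. DDX10, an RNA helicase of the nucleolus, fell by 0.71 and PPAN, a factor for the large ribosomal subunit, fell by 0.64. MYC targets had 10 of 30 lower and 2 higher (12 and 2 adjusted over the list alone), a median of -0.24 and an adjusted p of 0.0185. C1QBP, a mitochondrial matrix protein, fell by 0.58 and ODC1, the first enzyme of polyamine synthesis, fell by 0.55. Nuclear genes of oxidative phosphorylation had 10 of 43 lower (9 adjusted over the list alone), a median of -0.15 (-0.0821 without WT replicate 1) and an adjusted p of 0.0202, with SDHD of complex II at -0.55 and NDUFV2 of complex I at -0.47. Cytosolic ribosomal proteins had 5 of 80 lower, a median of -0.18 (0.01 without WT replicate 1) and an adjusted p of 0.0266. Adjusted over the list alone this edgeR count was 0, with 15 lower and 2 higher at an unadjusted p under 0.05. RPS3 of the small subunit fell by 0.46 and RPL3 of the large subunit fell by 0.40. Without KO replicate 1 their adjusted p was 0.116 and 0.104, without KO replicate 2 it was 0.198 and 0.25, and with the replicate number as a block it was 0.0808 and 0.0842, and RPL3 had 0.0632 with total library size only. NDUFV2 had an adjusted p of 0.0642 without KO replicate 2.

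These 9 calls, 5 up and 4 down, were made with the preset correlation of camera. The form with an estimated correlation also uses the few degrees of freedom of 4 libraries, so calls were hard to reach whatever the correlation. How much of the loss of calls came from the correlation was not separated. With an estimated correlation camera called 0 of the 24 lists, and 0 at an unadjusted p under 0.05, where antigen presentation had the lowest, 0.0899. The adjusted p was 0.896 for ribosomal proteins and 0.834 for each of the other 8 called lists with an estimated correlation. Fry called antigen presentation and cancer-testis antigens (adjusted p = 0.0165 each), and its mixed form called 23 lists. Calls were lost when 1 library was left out. Without WT replicate 1 the adjusted p was 0.0737 for EMT genes, 0.079 for glycan metabolism, 0.14 for oxidative phosphorylation and 0.934 for ribosomal proteins, whose median was then 0.01. Without WT replicate 2 it was 0.0953 for MYC targets. Without KO replicate 2 it was 0.1 for EMT genes, 0.0909 for glycan metabolism, MYC targets and oxidative phosphorylation, and 0.128 for ribosomal proteins. The call of ribosomal proteins was also lost among G1-like cells (adjusted p of 0.0544) and with a mitochondrial maximum of 10% (0.0836).

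**Figure D4:**
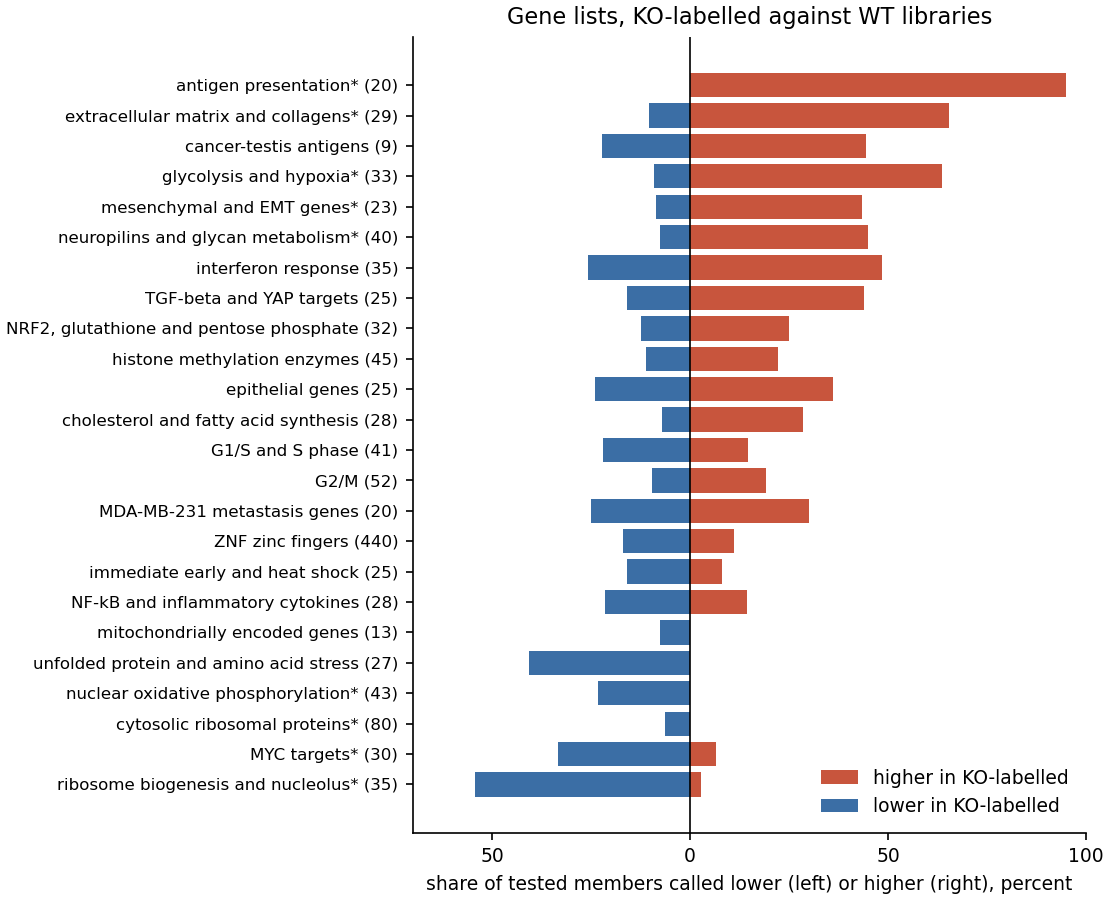
Share of the tested members of each list (number in brackets) called higher (right) or lower (left) in KO-labelled libraries, in percent, with an asterisk where camera with the preset correlation gave an adjusted p under 0.05. Antigen presentation has 19 of 20 members higher, and ribosome biogenesis has 19 of 35 lower.

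The remaining 15 lists were not called by camera. Interferon response genes moved both ways, with 17 of 35 higher and 9 lower (17 and 9 adjusted over the list alone, median 0.17, adjusted p of 0.162). OASL and IFIT1, effectors against viral RNA, fell by 1.77 and fell by 1.20. TGF-beta and YAP targets had 11 of 25 higher and 4 lower (11 and 4 adjusted over the list alone, adjusted p of 0.0538), with PMEPA1, a TGF-beta feedback inhibitor, at 1.51 and TGFBI, a matrix protein, at 1.08. Unfolded protein and amino acid stress had 11 of 27 lower (11 lower and 1 higher adjusted over the list alone, adjusted p of 0.0538), with PSAT1, an enzyme of serine synthesis, at -0.70 and DDIT3, a stress transcription factor, at -0.60. Epithelial genes had 9 of 25 higher and 6 lower (10 and 6 adjusted over the list alone, adjusted p of 0.56). DSP, a desmosomal protein, rose by 0.66 and CD24, a surface sialoglycoprotein, fell by 0.55.

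MDA-MB-231 metastasis genes had 6 of 20 higher and 5 lower (6 and 5 adjusted over the list alone, adjusted p of 0.958), and KISS1 fell by 0.91. Their median, mean and camera direction were down and fry's direction was up. NF-kB and inflammatory cytokines had 4 of 28 higher and 6 lower (6 and 7 adjusted over the list alone, adjusted p of 0.563), with IL24 lowest and SOD2, the mitochondrial superoxide dismutase, at -0.41, whose adjusted p was 0.0559 without KO replicate 1. Histone methylation enzymes, the class in which mdig has been studied, had 10 of 45 higher and 5 lower (10 and 5 adjusted over the list alone, adjusted p of 0.146). KDM5C, an H3K4 demethylase, rose by 0.86 and KDM4A, an H3K9 and H3K36 demethylase, by 0.58. Only 9 of 32 cancer-testis antigens were expressed enough to be tested, and 4 rose and 2 fell (4 and 2 adjusted over the list alone, adjusted p of 0.34), with SSX1 at 1.245.

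NRF2, glutathione and pentose phosphate genes had 8 of 32 higher and 4 lower (9 and 4 adjusted over the list alone, adjusted p of 0.162). AKR1C3, an aldo-keto reductase, rose by 1.56. Cholesterol and fatty acid synthesis had 8 of 28 higher and 2 lower (9 and 5 adjusted over the list alone, adjusted p of 0.403), with the sterol enzyme MSMO1 at 0.56. Immediate early and heat shock genes had 2 of 25 higher and 4 lower (2 and 3 adjusted over the list alone, adjusted p of 0.56), and the risers were the AP-1 subunits JUN at 0.58 and FOSB at 0.51. FOSB had an adjusted p of 0.0658 without KO replicate 1. Of 13 mitochondrially encoded genes only MT-ATP8, an ATP synthase subunit, was called, at -0.33 (adjusted p of 0.533 for the list). Its own adjusted p was 0.0747 without WT replicate 1, 0.283 without KO replicate 1, 0.0738 with total library size only and 0.083 with no mitochondrial maximum. Adjusted over the list alone this edgeR count was 0, with 1 lower at an unadjusted p under 0.05. ZNF zinc fingers had 49 of 440 higher and 75 lower (47 and 66 adjusted over the list alone, adjusted p of 0.218), with ZNF503 at 1.05 and ZNF827 at 0.96.

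The cell cycle lists did not move as groups. G1/S and S phase genes had 6 of 41 higher and 9 lower (6 and 9 adjusted over the list alone, adjusted p of 0.901), with the replication-linked genes WDR76 at 0.48 and NASP, a histone chaperone, at 0.46. G2/M genes had 10 of 52 higher and 5 lower (9 and 5 adjusted over the list alone, adjusted p of 0.622), with CENPE, a kinetochore motor, at 0.55 and HMGB2, a chromatin protein, at 0.52. For G1/S the mean was -0.01 and camera's direction down with a median of 0.00 and fry's direction up. For G2/M the median was -0.01 with a mean of 0.03 and camera's direction up. The share of cells scored as in S or G2/M was 73.1 ± 1.246% in WT and 68.2 ± 1.79% in KO-labelled libraries (SD, n = 2), a difference of -4.94 points with an exact permutation p of 0.333. That is the smallest p that 2 libraries against 2 can give, and phase scores also read free RNA, so no rate of cycling is read from them. Without thinning the shares were 73.2% and 75.02% in WT against 70.1% and 67.5% in KO-labelled libraries.

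The last comparison asked whether the libraries held cells with the profile of the other genotype. By a score built on the other pair of libraries, 9.97% (9.16 to 10.8%) and 5.74% (5.04 to 6.49%) of cells of WT replicates 1 and 2 fell on the KO-labelled side, a mean of 7.85 ± 2.99%. Of the cells of KO replicates 1 and 2, 16.0% (15.0 to 17.2%) and 14.6% (13.6 to 15.6%) fell on the WT side, a mean of 15.3 ± 1.04%. These came largely from KO subpopulation 2, of which 45.8% and 44.5% lay on the WT side, against 1.31% and 1.58% of subpopulation 1. In WT they came largely from subpopulation 1, of which 21.7% and 12.1% lay on the KO-labelled side, against 0.245% and 0.362% of subpopulation 2. PLCB4 was carried mainly by WT subpopulation 2 (49.1 and 52.2 CPM, against 2.31 and 2.21 CPM in WT subpopulation 1), and THY1 mainly by WT subpopulation 1 (log2 difference of -4.57, subpopulation 2 minus 1). Both stayed at or under 0.929% of their mean over WT libraries in both KO subpopulations. With limits that left out the cells in the middle, the means were 3.80% in WT and 8.84% in KO-labelled libraries.

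Markers of other cell types were scarce except those of the luminal list, and every cell carried at least 3 of the MDA-MB-231-like markers, of which VIM reached 5185 to 5975 CPM. Cells with at least 3 lymphocyte markers numbered 1 in WT replicate 1 and 0 in the other libraries, and no library held a cell with 3 erythroid, fibroblast, endothelial, basal or neural markers. A count of 0 among 4096 cells, the smallest library, allows a share of up to 0.0732%, which is that of 3 cells. CD3D, a T cell receptor chain in the lymphocyte list, was present at 4.06 and 3.85 CPM in WT against 0.0812 and 0.0400 CPM in KO-labelled libraries, and GAL, in the neural list, at 16.9 and 20.9 CPM in WT against 3.25 and 2.51 CPM in KO-labelled libraries. Myeloid markers reached 3 in 33, 26, 24 and 26 cells in the order WT 1, WT 2, KO 1 and KO 2, with the lysosomal protein CD68 at 35.3 to 41.1 CPM. Luminal epithelial markers reached 3 in 99.9% or more of cells, mainly from the keratin KRT18 at 1043 to 1436 CPM. Of the 10 markers in this list 2 stayed under 1 CPM, ESR1 at 0.0138 to 0.028 CPM and FOXA1 at 0.0148 to 0.0599 CPM. The rule of 3 markers was thus met without them and does not mark the cells as luminal. KRT8, KRT18, KRT19 and EPCAM of the luminal list also stand in the epithelial list, and 5 of the 8 MDA-MB-231-like markers also stand in the EMT list.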

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

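The comparisons with single subpopulations, without the 5% of cells with most UMIs and with the crossed pairing were added only after the data had been seen, and the others were fixed before. RIOX2 stayed higher in KO-labelled libraries and past the threshold in all 4 fits without 1 library (0.37 to 0.49) and in 10 other settings fixed beforehand (0.41 to 0.81, the last among G1-like cells, adjusted p from 4.44e-06 to 0.0018). The setting without doublet removal is left out of these numbers of settings, since no doublets had been removed and it changes nothing. A fit with 1 library in a group assumes that it varies like the other group. The number of called genes was 4629 to 6667 without 1 library, with 2423 to 3390 higher, 2206 to 3306 lower and 1214 to 1388 changed at least 2-fold. It was 5423 to 7856 in the other settings fixed beforehand, where 1007 (DESeq2) to 1544 genes changed at least 2-fold. With KO subpopulation 1 alone 2068 genes, and with WT subpopulation 2 alone 2094 genes, changed at least 2-fold, and the cause was not tested. Of the 6971 calls, 6064 kept call and direction with KO subpopulation 1 alone and 3407 with subpopulation 2 alone. The replicate number as a block kept 93.8% of calls, among 6842, and the crossed pairing gave 8069.

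Of the 54 named genes, 48 kept direction and call under all settings fixed beforehand and 21 also under those added later. None of them reversed in a setting fixed beforehand. With the total library size alone MT-ATP8 and RPL3 lost their call, with no mitochondrial maximum MT-ATP8, with the replicate block RPS3 and RPL3, and without 1 library these 3 genes, SOD2, FOSB or NDUFV2 did. Changes reversed with KO subpopulation 2 alone for RIOX2 (-1.47), APCDD1L-DT (-0.33), TNC (-0.98), MMP14 (-0.63), CD24 (0.062), KISS1 (0.40), HAS2 (-0.87), HS3ST1 (-0.094), SOD2 (0.025), KDM5C (-0.33), CA12 (-0.067), JUN (-0.24) and MT-ATP8 (0.094). They reversed with KO subpopulation 1 alone for SSX1 (-1.96), with WT subpopulation 1 alone for DDX10 (0.093) and with WT subpopulation 2 alone for CD24 (0.20). Fewer cells entered these fits, and the cause was not tested.

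The number of lists called was 5 to 10 without 1 library and 0 with the correlation of camera estimated, at 0.0342 to 0.451 for the 9 called lists against the preset 0.01. With KO subpopulation 2 alone the medians of EMT genes (-0.12), glycolysis and hypoxia (-0.16) and mitochondrially encoded genes (0.25) reversed, and the calls of the former 2 were lost (adjusted p of 0.135 and 0.115). Calls were also lost there for extracellular matrix (median 0.15, adjusted p of 0.399), glycan metabolism (0.999), ribosome biogenesis (0.0527), MYC targets (0.0663) and oxidative phosphorylation (0.115). With WT subpopulation 1 alone they were lost for EMT genes (0.165), ribosome biogenesis (median -0.07, adjusted p of 0.431), MYC targets (0.147), oxidative phosphorylation (0.0929) and ribosomal proteins (0.163), with KO subpopulation 1 alone for ribosomal proteins (0.224) and with WT subpopulation 2 alone for glycan metabolism (0.065). The cause was not tested. The share of cells in S or G2/M was lower in KO-labelled libraries by -6.20 to -3.67 points without 1 library and by -6.56 to -4.41 points in 5 distinct other settings, since minima of 2000 and 5000 UMIs scored the same cells. Cells with a profile of the other genotype came to 3.80% in WT and 8.84% in KO-labelled libraries when cells in the middle were left out, which removes cells by construction, and to 13.6% in KO-labelled libraries with no mitochondrial maximum, where the cause was not tested. In counts simulated with 2 libraries per group, 26% of genes with the smallest change were recovered, and depth was not varied there. Thinning to the smallest library kept 95.2% of the calls, and lower depths were not tried.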

Other observations

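The split into subpopulations, the comparisons between them and the tests of free RNA, of WT cells mixed into KO-labelled libraries and of cell depth were chosen only after the results they concern had been seen. Within the KO-labelled libraries, the subpopulation with little RIOX2 also had less of the glycolysis and hypoxia genes, of which 30 of 33 were lower there (median log2 difference of -0.75, camera adjusted p of 7.0e-08). Extracellular matrix genes were lower for 23 of 29 members (adjusted p of 6.01e-04) and EMT genes for 18 of 23 (adjusted p of 7.68e-04). Antigen presentation was lower for 14 of 20 members (adjusted p of 0.0239). Genes of these lists could take part in defining the split, so the values describe it. Mitochondrially encoded genes and ribosomal proteins took no part in the split. The former were higher in subpopulation 2 for 11 of 13 members (median 0.57, adjusted p of 0.00179) and the latter lower for 50 of 80 (median -0.07, adjusted p of 0.0146). Ribosome biogenesis genes were higher there for 25 of 35 members (median 0.13, adjusted p of 0.0266). These p-values come from the preset correlation of camera.

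Chromosomes differed between the KO subpopulations as well. The median log2 difference, subpopulation 2 minus 1, was -0.46 over 545 genes of chromosome 12 (interquartile range of -0.64 to -0.29) and -0.45 over 313 genes of chromosome 15 (-0.61 to -0.27). Between the WT subpopulations the corresponding medians were 0.00 and -0.01, and chromosome 6 stood at -0.26 and chromosome 19 at 0.19.

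RIOX2 differed 5.13-fold between the KO subpopulations. Free RNA held RIOX2 at 61.15% and 60.6% of its level in subpopulation 1 of the same library (highest upper 95% limit of 67.1%). It could not have lifted subpopulation 1 above its own level, which argues against free RNA as the source of the difference. Subpopulation 2 held 0.605 and 0.62 RIOX2 UMIs per cell in the KO-labelled libraries, where free RNA was estimated to give 0.00678 and 0.00864. This argues against free RNA as the source of most of them, if droplets with cells hold as much free RNA as those without. That condition was not measured, so the exact share stays open. The 52 genes within 10 Mb of RIOX2 shifted by a median of -0.24 (interquartile range of -0.63 to 0.02) against -2.36 for RIOX2, which argues against a copy number change of that size. The 11 nearest genes with a value lay between -1.16 and 0.118, which also goes against a change of that size in a smaller region that takes them in. Of these, 9 were lower in subpopulation 2, with a median of -0.609 against -0.0675 over chromosome 3, so a smaller local change as part of the difference stays open. A change of RIOX2 alone was not tested. WT cells mixed into the KO-labelled libraries would bring THY1 from WT subpopulation 1 or PLCB4 from WT subpopulation 2. Both reached at most 0.929% of their mean WT level in either KO subpopulation. These genes were picked from the same data as the largest falls, so low values in KO-labelled libraries were set by that choice. The values still argue against cells with either gene at its WT level as a large part of a KO subpopulation. WT cells that carry neither gene were not tested. No biological explanation of the difference was tested.

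Many genes differed between KO-labelled and WT libraries, 1359 of them by at least 2-fold. Other proportions of the WT subpopulations are argued against as the whole source, since 76.4% of these genes (1038) had a level in both KO-labelled libraries outside the range of all WT subpopulation values. Chromosome explained 13.0% of the variance of log2 changes over 9898 genes, where the highest of 1000 permutations gave 0.516%, consistent with copy number differences as part of the changes. After the median of the 100 nearest genes was subtracted, 88.6% of the 2-fold genes with a position (1151 of 1299) kept a 2-fold change. Among genes of at least 5 CPM, the set on which this test was first run, 81.6% (133 of 163) did. Chromosome medians reached at most 0.36, too small to make a 2-fold change, so most of these genes had to keep theirs. The shares that kept a 2-fold change therefore decide nothing. The small size of the medians argues against differences of whole chromosomes as the source of all the 2-fold changes. Gains or losses of shorter stretches, which a median of 100 genes does not show, stay open. Loss of mdig and divergence of the KO-labelled line from its parent for other reasons both stay open, because the labels name no second clone and no rescue.

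In WT cells RIOX2 followed the nucleolar genes from cell to cell, with a median correlation above that of all 10000 random lists in both libraries. This was not particular to that list, since MYC targets, which share 3 members with it, and G1/S genes also lay at percentile 100 in both. At the other end, interferon response, G2/M and glycolysis and hypoxia genes lay at percentile 0 in both. Random lists were drawn gene by gene at like levels, so they lack the shared variation of a real list. Their spread is therefore too narrow, and an extreme percentile is easily reached. After every cell was thinned to equal depth the median correlation of the nucleolar list fell from 0.112 and 0.103 to 0.0356 and 0.0339, with percentile 100 before and after (typical random lists had 0.00459 and 0.00431 after thinning). Within the limit of these random lists, what was left argues against UMI depth as the whole source. Thinning equalizes the UMIs of cells and not their composition, so size of the cell stays open. Thinning also makes counts noisier, so how much of the fall is due to depth was not separated. MYC targets stayed there as well (0.0309 and 0.0311), and G1/S genes were at percentiles 100 and 96.0. Among G1-like cells alone the nucleolar list again stayed at percentile 100 (median r of 0.0399 and 0.0589). This was set beforehand to speak against cell cycle phase, but G1/S genes stayed at percentiles 99.99 and 99.64 in the same cells (median r of 0.0301 and 0.0267) and G2/M genes were at 77.8 and 100. Taking G1-like cells thus did not remove what varies with the cycle, and cell cycle phase stays open. In thinned KO-labelled cells the percentiles of the nucleolar list were 98.2 and 87.2, with 99.72 and 99.98 within subpopulation 1 and 94.07 and 51.09 within subpopulation 2, and a difference between the genotypes was not tested. The correlations are weak, and no biological explanation of them was tested.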
